A study of Danio rerio with 9 samples.

How the data were processed

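Gene expression was measured by RNA sequencing in 9 libraries from zebrafish of strain EK at 13 days after fertilization. Notochord sheath cells were sorted by fluorescence into col9a2+, double-positive (col9a2 and entpd5a) and entpd5a+ populations, with 3 replicates each, and ultra-low-input cDNA libraries were amplified from them. The labels do not state whether replicates are separate animals, pools or sorts, so p values measure the spread between these samples. The design describes transgenic fish, whereas the genotype label reads wild type. The deposited files hold raw read counts per Ensembl gene. Per the submitters' processing notes reads were aligned to GRCz10 with HISAT2 and counted with HTSeq, and versions and strand setting are not stated. Reads shared by near-identical genes were not traced, which concerns pairs such as muc5.1 and muc5.2.

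Each file held 32266 gene IDs, of which 26433 (81.92%) had a gene name in the name table. Many names are in capitals without the zebrafish paralog letter, and where several IDs share a name the ID is printed. ENTPD5 is the name of 1 ID, and the table does not separate entpd5a from entpd5b. Chromosome positions were not used here.

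Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 3 populations (19039 genes), and libraries were scaled with TMM factors. A quasi-likelihood model with a coefficient per population and robust dispersion was fitted to all 9 libraries, and each pair of populations was compared with a two-sided F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use the TMM factors, and log2 CPM values a prior count of 2. The common dispersion was 0.588. Pearson correlations of log2 CPM across genes lay between 0.818 and 0.904 for library pairs within a population and between 0.746 and 0.877 across populations, and genes are not independent replicates. Library totals ranged from 39955994 to 81471212 counts. Ratios for genes with up to 3 counts in a population carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, since amplified reads are not independent molecules.

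The lists, comparisons, named-gene rule and most alternatives were fixed before the data were examined. Genes above both, below both and stepwise are intersections of the pairwise calls. The axis position projects log2 CPM onto the line between the col9a2+ and entpd5a+ means. There were 25 gene lists: cartilage, bone, mineral and phosphate handling, Notch, retinoic acid, BMP and TGF-beta, hedgehog, Wnt, FGF, notochord, procollagen processing and secretion, matrix remodelling, cell cycle, immediate early and heat shock, tendon with fibroblast and sclerotome, osteoclast and leukocyte, muscle, epidermis, endothelial, erythroid, neural and glial, pigment, mitochondrially encoded, Hox, and cytosolic ribosomal proteins. Of their entries 330 matched a gene name exactly, 317 in another case and 188 without the paralog letter. Another 132 came from naming rules, 42 were ambiguous and 87 had no match. Some genes belong to several lists, such as the SHH genes in the hedgehog and notochord lists. Lists were tested with camera from limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over 75 tests, and again with an estimated correlation and with fry. Camera called 34 of the 75 tests, and none of the 34 kept its call with an estimated correlation, where adjusted p values were 0.201 or higher.

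Named genes are the sort genes, and per comparison the 6 largest rises and 6 largest falls among called genes with at least 20 CPM in the higher population, no overlap between libraries and a proper gene symbol. They include up to 4 called members per list with the smallest adjusted p, at least 1 per direction, and the 5 genes per pattern with the largest smaller difference.

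Same-numbered col9a2+ and double-positive libraries shared deviations from their population means (r across genes 0.18, 0.22 and 0.33), whereas same-numbered entpd5a+ libraries did not throughout (r of -0.11 and -0.10 for number 2). Replicate number was therefore used as a block only as an alternative. Other alternatives were RLE and upper-quartile factors, no count filter, a mean of at least 10 CPM, each library left out, DESeq2 1.42.0, fits of 6 libraries, and a minimum fold of 1.5. Alternatives chosen after seeing the data were a term for the 4 deeper libraries against the 5 shallower ones, divided at the largest gap in library totals, in the gene, list and axis results, the 5 shallower libraries alone, and the block in the 6 col9a2+ and double-positive libraries.

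The test was tried on simulated data with 200 changed genes per comparison, drawn from genes with a mean of at least 5 CPM. It recovered 0% of 2-fold changes, 12% to 20% of 4-fold, 56% to 64% of 8-fold and 80% to 84% of 16-fold changes. Of 83, 86 and 76 calls 5, 2 and 2 were false. The smallest absolute log2 fold changes called in the real comparisons were 1.13, 1.17 and 1.03.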

Results

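RNA was sequenced from cells of the zebrafish notochord sheath, the epithelial layer around the vacuolated core of the notochord, in fish 13 days after fertilization. Fluorescence-activated sorting gave 3 populations with 3 libraries each. The col9a2+ population carried a reporter for col9a2, which encodes a chain of cartilage collagen IX. The entpd5a+ population carried a reporter for entpd5a, which encodes an ectonucleoside phosphate-releasing enzyme that bone mineralization requires. The double-positive population carried both. The study's title places these populations in the question of how segments of the sheath guide the pattern of the spine. The comparisons therefore ask which genes separate col9a2+ from entpd5a+ cells, and where the double-positive cells stand.

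The files held counts for 32266 gene IDs per library, and 19039 genes passed the count filter. The col9a2+ libraries totalled 39955994, 43459950 and 75825103 counts, the double-positive libraries 41687120, 46025035 and 74690602, and the entpd5a+ libraries 46708240, 81471212 and 67788360. Libraries detected between 17850 and 21996 genes. The 4 deeper libraries (col9a2+ 3, double-positive 3, entpd5a+ 2 and 3), with at least 67788360 counts, also differed in content from the 5 shallower ones, with at most 46708240. The heat shock gene hsp70l lay between 17950 and 27150 CPM (counts scaled to the library size) in those 4 libraries and between 277 and 909 CPM in the 5 others. Cytosolic ribosomal proteins took between 1.97% and 2.79% of counts in the 4 libraries and between 5.58% and 9.69% in the 5. Double-positive library 1 held the endothelial genes kdrl at 62.0 CPM and cdh5 at 67.3 CPM, against at most 7.53 and 1.95 CPM elsewhere. In what follows levels are mean CPM ± SD (n = 3 libraries), fold changes are log2 ± standard error, and adjusted p values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

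The genes used for sorting followed the labels. COL9A2 stood at 9561 ± 1916 CPM in col9a2+ libraries, 1272 ± 406 CPM in double-positive and 189 ± 208 CPM in entpd5a+ libraries. ENTPD5 stood at 278 ± 163 CPM in col9a2+ libraries, 14030 ± 4230 CPM in double-positive and 4257 ± 1294 CPM in entpd5a+ libraries. Between entpd5a+ and col9a2+ cells COL9A2 fell by 5.66 ± 0.89 on the log2 scale (adjusted p = 0.00729, and -7.12 without entpd5a+ library 1), and ENTPD5 rose by 3.94 ± 0.63 (adjusted p = 0.00804). ENTPD5 also rose by 5.66 ± 0.69 from col9a2+ to double-positive cells (adjusted p = 0.00412). COL9A2 differed by -2.91 ± 0.78 between double-positive and col9a2+ cells and by -2.75 ± 0.77 between entpd5a+ and double-positive cells, with adjusted p = 0.0787 and 0.0683. Neither passed the test of all 9 libraries, although no libraries overlapped in either pair. With the replicate number as a block in all 9 libraries, neither COL9A2 difference passed. The following fits were chosen after the data were seen. With that block in the 6 col9a2+ and double-positive libraries alone, COL9A2 fell by 2.98 in double-positive cells (adjusted p = 6.96e-04). With the depth groups as a term, both COL9A2 differences passed (adjusted p = 0.0391 and 0.0329). ENTPD5 was 3.30-fold lower in entpd5a+ than in double-positive cells, a difference that did not pass the test (adjusted p = 0.122).

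Across all genes the populations separated along principal components 1 and 2, which held 27% and 23.3% of the variance. On the line from the col9a2+ mean at 0 to the entpd5a+ mean at 1, the double-positive libraries lay at 0.508, 0.375 and 0.564, a mean of 0.483 ± 0.097 (SD, n = 3). Over the 955 genes that differed between the ends the mean was 0.462 ± 0.109. A population unrelated to both ends would also project near the middle of this line. Neither mean therefore shows that the double-positive cells are intermediate. On component 1 every double-positive library lay to the same side of all col9a2+ and entpd5a+ libraries, not between them. Component 1 also followed depth, as the deeper libraries lay lower on it than the shallower ones inside each population. Double-positive library 1, which held endothelial transcripts, lay furthest out. Positions on component 1 therefore do not decide whether the double-positive cells are intermediate. With the depth groups as a term in the fit, 891 of the 955 calls between entpd5a+ and col9a2+ cells were kept in the same direction, as were 672 of 674 between double-positive and col9a2+ cells and 1187 of 1239 between entpd5a+ and double-positive cells. An F test over the 3 populations called 1792 genes. That count was 1084 without col9a2+ library 2, 1122 without entpd5a+ library 2 and 1181 without col9a2+ library 1.

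**Figure D1:**
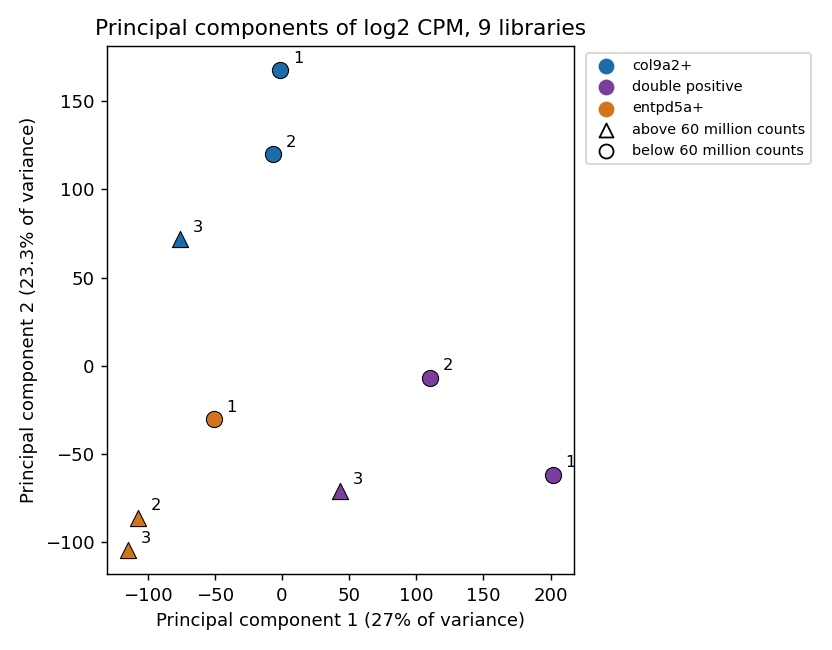
Principal components 1 and 2 of log2 CPM for the 9 libraries, coloured by population and numbered by replicate, with triangles for the 4 deeper libraries. The double-positive libraries sit at the right of component 1, and the col9a2+ and entpd5a+ libraries part along component 2.

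**Figure D2:**
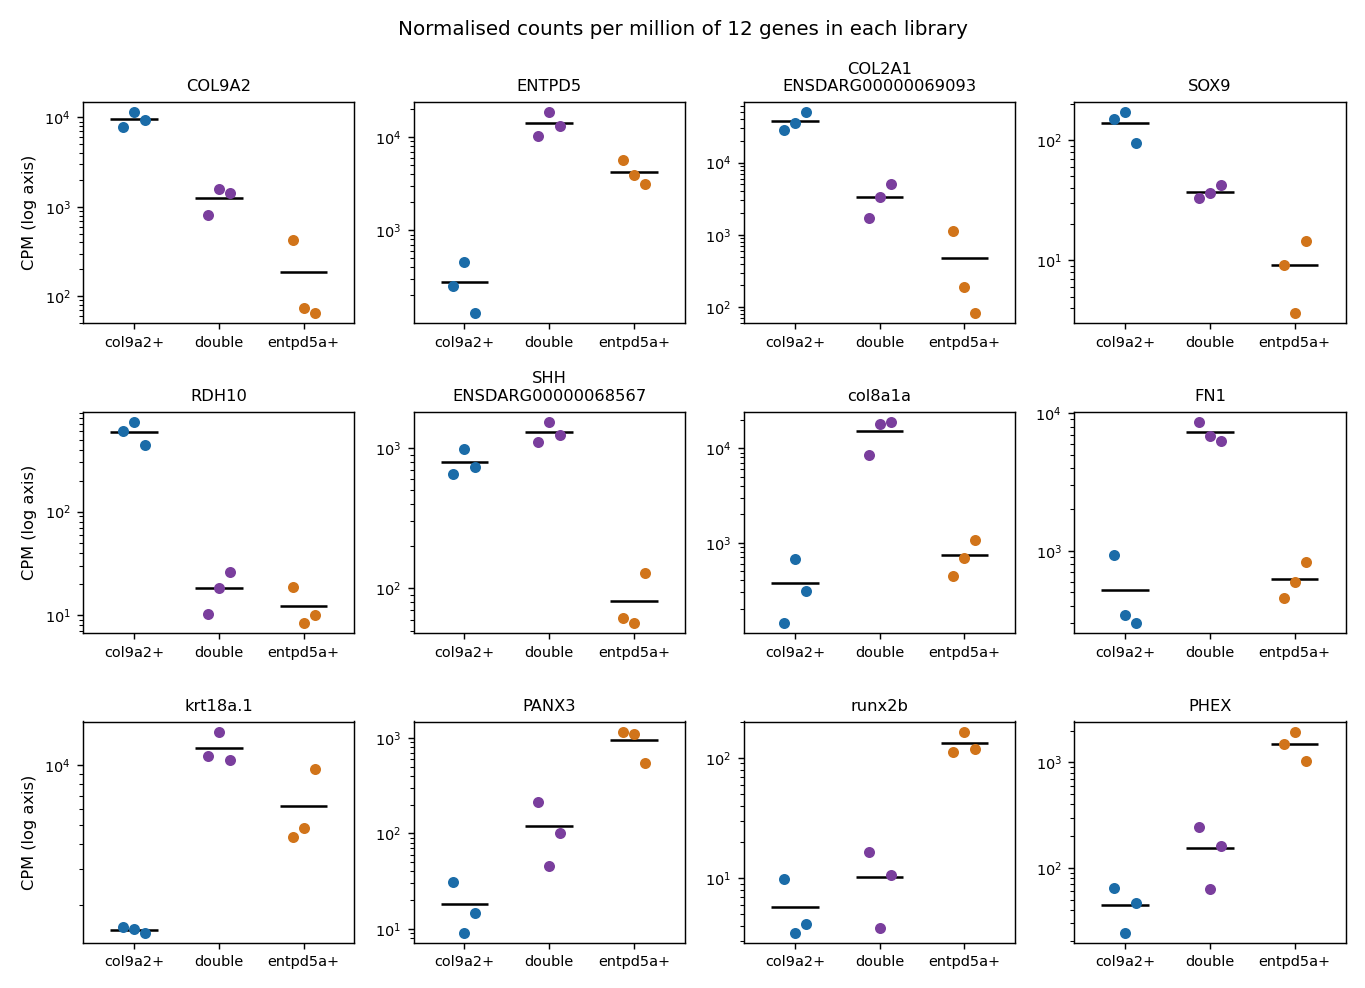
CPM on a log axis of 12 genes in each library, with a point per library and a black line at the mean of 3. COL9A2, COL2A1 and SOX9 are highest in col9a2+ libraries, col8a1a and FN1 in double-positive libraries, and PANX3, runx2b and PHEX in entpd5a+ libraries.

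The comparison of entpd5a+ with col9a2+ cells asks which genes separate the populations that carry either reporter alone. In entpd5a+ cells 17 of 27 bone genes rose and 15 of 29 cartilage genes fell. PANX3, a channel of osteoblasts and hypertrophic chondrocytes, rose from 18.3 ± 11.5 to 937.9 ± 342.3 CPM, by 5.68 ± 0.77 (adjusted p = 0.00445, and 6.30 without col9a2+ library 1). COL2A1 (ENSDARG00000069093), the main cartilage collagen, went from 38170 ± 11170 to 471 ± 584 CPM and fell by 6.34 ± 1.12 (adjusted p = 0.0121, and -8.14 without entpd5a+ library 1). The test called 955 genes, 510 higher and 445 lower in entpd5a+ cells. In every called gene the libraries of the populations did not overlap, which chance gives in 10% of genes and which held for 24.7% of all genes tested. Calling selects such genes, so the lack of overlap adds no support to the calls, here or in the other comparisons.

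Of 27 measured osteoblast factors and bone matrix genes, 17 rose and none fell in entpd5a+ cells, and 22 rose adjusted over the list alone. The transcription factor runx2b rose from 5.79 ± 3.43 to 133.0 ± 28.8 CPM, by 4.52 ± 0.62 (adjusted p = 0.00464, and 5.12 without col9a2+ library 1). The mineral-binding matrix gene scpp1 rose by 5.17 ± 0.60 (adjusted p = 0.0027), and the fibrillar collagen gene col5a2b by 5.61 ± 0.73 (adjusted p = 0.00401). The camera test placed this list above other genes (adjusted p = 8.81e-19), but not with an estimated correlation (adjusted p = 0.201). Of 28 measured genes of mineral and phosphate handling, 8 rose and none fell, and 9 rose and 2 fell adjusted over the list alone. Here PHOSPHO1, a phosphatase of matrix vesicles, rose by 5.68 ± 0.73, PHEX, a mineralization peptidase, by 5.07 ± 0.65, and SMPD3, a neutral sphingomyelinase, by 5.78 ± 0.85. Their adjusted p values were 0.004, 0.004 and 0.00575, and the rise of SMPD3 was 6.49 without col9a2+ library 1 and 5.11 without entpd5a+ library 2. The exchanger gene slc8a4b rose 57.6-fold to 46.5 ± 22.7 CPM (adjusted p = 0.00257).

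Of 29 measured cartilage genes, 15 fell and 1 rose in entpd5a+ cells, and 17 fell and 3 rose adjusted over the list alone. SOX9, a transcription factor that drives cartilage formation, fell by 3.93 ± 0.51 from 138.6 ± 40.1 CPM (adjusted p = 0.004). The matrix genes chad and MATN3 (ENSDARG00000069265) fell by 4.63 ± 0.47 and 3.84 ± 0.50 (adjusted p = 0.00177 and 0.004). The exception was col11a1b, a collagen XI chain, which rose by 3.32 ± 0.73 (adjusted p = 0.0305). Camera put the list below other genes (adjusted p = 4.11e-12), but not with an estimated correlation (adjusted p = 0.201). Among called genes that met the rule for named genes, the largest falls included colgalt2a, a collagen galactosyltransferase gene, at 149-fold (adjusted p = 0.0263). They also included col9a1b, another collagen IX chain, at 102-fold (adjusted p = 0.0139). WNT16 was 82.7-fold lower (adjusted p = 0.00485), NANS, a sialic acid synthase gene, 92.3-fold (adjusted p = 0.0378), and fer1l4 69.2-fold (adjusted p = 0.0354). Their size depended on single libraries, as the log2 differences of colgalt2a, col9a1b and COL2A1 (ENSDARG00000069093) were -9.67, -8.79 and -8.14 without entpd5a+ library 1, and those of NANS and fer1l4 -9.37 and -7.28 without entpd5a+ library 2. Among the largest rises were those of HAS1, a hyaluronan synthase gene, MDGA2, PLTP and tmem119a. PLTP reached 547.6 ± 231.3 CPM, a 56.8-fold rise (adjusted p = 0.00177), and tmem119a 344.4 ± 130.9 CPM, a 53.5-fold rise (adjusted p = 0.0027). HAS1 stood at 0.5403, 11.25 and 95.4 CPM in the entpd5a+ libraries, with 5 counts in the col9a2+ libraries together, and rose by a log2 difference of 10.01 (adjusted p = 0.0208). That was 7.26 without entpd5a+ library 3, 9.21 without col9a2+ library 3 and 10.61 without entpd5a+ library 1, and 2 counts remain without col9a2+ library 2. MDGA2 reached 20.1 ± 6.04 CPM and rose by 6.53 (adjusted p = 0.0462), and by 9.15 without col9a2+ library 2 and 5.94 without col9a2+ library 1. With the 2 depth groups as a term in the fit, neither HAS1 nor MDGA2 nor NANS passed the test (adjusted p = 0.082, 0.0685 and 0.052).

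Signalling genes divided in direction. In the hedgehog list 5 of 20 measured genes rose and 2 fell. The 2 genes named SHH (ENSDARG00000068567 and ENSDARG00000038867) fell by 3.27 ± 0.47 and 3.56 ± 0.53 (adjusted p = 0.0051 and 0.00598), whereas ihha rose by 4.91 ± 0.68 (adjusted p = 0.00464) and the target gene GLI1 by 4.36 ± 0.77 (adjusted p = 0.0117). Both SHH genes are also in the notochord list, so their falls count in both lists, here and against double-positive cells. In the BMP and TGF-beta list 12 of 53 rose and 4 fell, including a rise of the ligand genes BMP5 by 4.17 ± 0.52 and BMP6 by 3.02 ± 0.44, and a fall of ID4 by 3.31 ± 0.48 (adjusted p = 0.00364, 0.00552 and 0.00562). The retinoic acid list had 2 rises and 6 falls among 27. RDH10, which makes retinaldehyde, fell by 5.59 ± 0.55 (adjusted p = 0.00177), ALDH1A2, which makes retinoic acid, fell by 2.54 ± 0.34 (adjusted p = 0.00407), and the receptor gene RARG rose by 2.18 ± 0.37 (adjusted p = 0.00991). In the Wnt list 6 of 48 rose and 2 fell, with dkk1a up 21.2-fold (adjusted p = 0.00177) and wnt4b down 24.2-fold (adjusted p = 0.00605). In the FGF list 3 of 31 rose and 1 fell, with fgfbp2a 46.8-fold higher (adjusted p = 0.00609) and FGFR1 5.27-fold higher (adjusted p = 0.00657). In the Notch list 1 of 36 rose, RFNG, by 2.43 ± 0.45 (adjusted p = 0.0142). The log2 difference of ID4 was -4.07 without entpd5a+ library 3, that of ihha 4.13 without entpd5a+ library 2 and that of wnt4b -3.91 without col9a2+ library 3. Notch list medians were highest in the entpd5a+ libraries 2 and 3, at 1.15 and 1.88 against 0.33 in library 1, and those are deeper libraries.

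Of 27 notochord genes 7 fell and 2 rose in entpd5a+ cells. TBXT, a transcription factor of the notochord, fell by 2.83 ± 0.52 (adjusted p = 0.0142), while krt18b rose by 2.65 ± 0.48 (adjusted p = 0.0133). Of 30 tendon, fibroblast and sclerotome markers 8 rose and none fell, including the tendon gene TNMD by 3.23 ± 0.63 and the mesenchymal factor foxc1b by 3.91 ± 0.73 (adjusted p = 0.0188 and 0.0145). TNMD differed by 3.89 without col9a2+ library 3, and foxc1b by 4.50 without col9a2+ library 1 and 3.23 without entpd5a+ library 3. Of 55 matrix remodelling genes 8 rose and 5 fell. The basement membrane collagens col4a5 and col4a6 fell by 2.89 ± 0.30 and 3.47 ± 0.31 (adjusted p = 0.00177 for each), and MMP14, a membrane collagenase, rose by 2.46 ± 0.36 (adjusted p = 0.00545). Of 46 Hox genes 3 rose and none fell, namely HOXB13 (22.4-fold, adjusted p = 0.00186), HOXC13 (6.68-fold, adjusted p = 0.0191) and hoxa13a (10.9-fold, adjusted p = 0.0278, and 0.0655 with the depth groups as a term).

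The count of 955 genes was 353 without col9a2+ library 2, 403 without entpd5a+ library 2, 483 without col9a2+ library 1, 574 without col9a2+ library 3 and 202 in the 5 shallower libraries alone, where entpd5a+ has 1 library that is assumed to vary like the other groups. Of 68 genes named by rule 40 kept their calls without each library in turn, and the fold of 21 moved by over 1.5 times without at least 1 library. Of those described here, the calls of HAS1, MDGA2, colgalt2a, col9a1b, NANS, COL2A1, fer1l4, col11a1b, GLI1, RARG, RFNG, TBXT, krt18b, TNMD, foxc1b, HOXC13 and hoxa13a were lost without at least 1 library.

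The comparison of double-positive with col9a2+ cells asks which genes separate cells with both reporters from cells with the col9a2 reporter alone. All libraries are from fish of the same age, so an order of the populations in time was not tested. In double-positive cells 4 of 27 notochord genes rose, while 9 of 29 cartilage genes and 9 of 40 epidermis markers fell. The collagen VIII gene col8a1a rose from 375.8 ± 273.4 to 15220 ± 5842 CPM, by 5.34 ± 0.79 (adjusted p = 0.00761), and FN1, which encodes fibronectin, from 524 ± 353 to 7247 ± 1252 CPM, by 3.79 ± 0.60 (adjusted p = 0.0102). The rise of col8a1a was 6.08 without col9a2+ library 2, and that of FN1 4.49 without col9a2+ library 1. The mucin gene muc5.2 fell from 1931 ± 1056 to 2.25 ± 0.766 CPM (adjusted p = 0.0219). The test called 674 genes, 319 higher and 355 lower, again with no overlap between libraries in any of them, against 24.4% of all genes tested.

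Of 27 measured bone genes 1 rose, RUNX2, by 2.35 ± 0.55 (adjusted p = 0.0465), and none fell, while adjusted over the list alone 10 rose and 2 fell. The median log2 difference of the bone list was 1.46, and camera put the list higher (adjusted p = 0.00116), but not with an estimated correlation (adjusted p = 0.593). Of 28 mineral and phosphate genes 4 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone. The pyrophosphate-producing enzyme gene enpp1 rose by 2.84 ± 0.47 to 1350 ± 412 CPM (adjusted p = 0.0115), and the phosphate transporter gene SLC20A1 (ENSDARG00000020114) by 3.92 ± 0.69 (adjusted p = 0.0146). Camera put the mineral list higher (adjusted p = 1.35e-04), but not with an estimated correlation (adjusted p = 0.201).

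Of 29 cartilage genes 9 fell and 1 rose, and 20 fell and 2 rose adjusted over the list alone. The other COL2A1 copy (ENSDARG00000011407) fell by 4.21 ± 0.71 (adjusted p = 0.0126), MATN4, a cartilage matrix adaptor, by 3.82 ± 0.49 (adjusted p = 0.00525), and the factor SOX5 by 2.08 ± 0.33 (adjusted p = 0.0104). The proteoglycan gene snorc rose by 2.25 ± 0.48 to 3591 ± 1280 CPM (adjusted p = 0.0327). Camera put the list lower (adjusted p = 4.61e-08), but not with an estimated correlation (adjusted p = 0.201). In the notochord list 4 of 27 rose and none fell. Besides col8a1a these were loxl5b, a lysyl oxidase gene, by 5.29 ± 0.68, and the keratin genes krt18a.1 by 3.01 ± 0.52 and krt8 by 1.93 ± 0.41 (adjusted p = 0.00525, 0.0128 and 0.0307). Single libraries moved the log2 differences of COL2A1 (ENSDARG00000011407) and MATN4 to -4.87 and -4.45, without double-positive library 3, and of col8a1a and loxl5b to 6.08 and 5.89, without col9a2+ library 2. Of 55 matrix remodelling genes 4 rose and 6 fell, and camera put the list lower (adjusted p = 0.0294), but not with an estimated correlation (adjusted p = 0.593). HTRA1, a secreted protease, rose by 5.10 ± 0.45 (adjusted p = 0.0014), and the matrix proteoglycan gene FMOD fell by 3.33 ± 0.53 (adjusted p = 0.0102).

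Retinoid genes were again split, with 4 rises and 2 falls among 27. RDH10 fell by 5.04 ± 0.53 and the retinol receptor gene STRA6 by 6.33 ± 0.88, while RARG rose by 2.59 ± 0.38 and CYP26B1, which degrades retinoic acid, by 3.80 ± 0.69 (adjusted p = 0.00225, 0.0064, 0.00698 and 0.0172). In the BMP and TGF-beta list 9 of 53 rose and 3 fell. BMP3 rose from 55.2 ± 38.0 to 1983 ± 492 CPM, by 5.17 ± 0.62, the antagonist gene nog2 by 4.80 ± 0.58 and the co-receptor gene TGFBR3 by 2.76 ± 0.37 (adjusted p = 0.0041, 0.00412 and 0.00545). In the Wnt list 9 of 48 rose and 2 fell, with dkk1a up 36.2-fold (adjusted p = 0.0014), TCF7L2 up 11.1-fold (adjusted p = 0.00343) and wnt4b down 41.7-fold (adjusted p = 0.00545). In the hedgehog list ihhb alone passed, of 20 measured, with a rise of 2.49 ± 0.45 (adjusted p = 0.0161). In the FGF list 2 of 31 rose and 2 fell, among them SPRY2, a feedback inhibitor, which fell by 1.79 ± 0.31 (adjusted p = 0.013). In the Notch list 1 of 36 rose, NOTCH1, by 3.28 ± 0.68 (adjusted p = 0.0296). Without col9a2+ library 3 the log2 differences of NOTCH1 and wnt4b were 3.99 and -4.69, and BMP3 and STRA6 differed by 5.89 without col9a2+ library 2 and by -6.98 without double-positive library 3.

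Of 40 epidermis markers 9 fell and 1 rose, with falls of the adhesion genes cdh1 by 3.53 ± 0.53 and epcam by 4.61 ± 0.74 (adjusted p = 0.00844 and 0.0104, and -5.61 for epcam without double-positive library 3). Camera put the list lower (adjusted p = 1.23e-06), but not with an estimated correlation (adjusted p = 0.481). Its medians in double-positive libraries 1, 2 and 3 were -2.50, -2.91 and 0.27, against 0.48, 1.02 and 1.94 in the col9a2+ libraries. Of 43 cell cycle genes 4 fell and none rose, and 11 fell adjusted over the list alone, with mki67 down 3.41-fold (adjusted p = 0.0455) and MCM4 down 2.65-fold (adjusted p = 0.0195). Camera put the cell cycle list lower (adjusted p = 8.21e-09), but not with an estimated correlation (adjusted p = 0.213). Of 46 Hox genes 4 fell and none rose, with HOXA11 down 9.46-fold (adjusted p = 0.0182, and a log2 difference of -3.87 without double-positive library 1). Of 30 tendon, fibroblast and sclerotome markers 2 fell and 1 rose, the falls being those of the 2 PRRX1 genes, ENSDARG00000042027 by 4.09 ± 0.41 and ENSDARG00000033971 by 2.20 ± 0.46 (adjusted p = 0.00208 and 0.0301).

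Among named genes of at least 20 CPM in the higher population, the largest rises were those of PRKG2, a cGMP-dependent kinase gene, optc, a small leucine-rich proteoglycan gene, RASSF4, the retinol esterification gene lratb.2, the somite segmentation factor mespbb and the calcium sensor gene hpcal4. Of these mespbb reached the highest level, 865.4 ± 121.1 CPM against 8.82 ± 4.58 CPM (98.2-fold, adjusted p = 0.0104), followed by lratb.2 at 162.4 ± 26.5 CPM (157-fold, adjusted p = 0.00698). The other largest rises took hpcal4 to 58.7 ± 24.9, optc to 36.5 ± 11.4, RASSF4 to 24.3 ± 8.77 and PRKG2 to 20.2 ± 6.50 CPM (adjusted p = 0.00225, 0.0115, 0.0422 and 0.0437). The largest falls were those of MFAP4, muc5.1, the polarity gene crb3b, the tight junction gene oclnb, muc5.2 and fgfbp2b. Among the col9a2+ libraries all of these were lowest in library 3. In col9a2+ libraries 1, 2 and 3 MFAP4 stood at 61.19, 57.02 and 5.558 CPM and muc5.1 at 625.6, 316.2 and 81.42 CPM. Which cells carried these transcripts was not tested. MFAP4 and oclnb had 3 counts in the double-positive libraries together, a ratio of 1628 (95% exact counting interval 556.9 to 7899) and 992 (339.2 to 4813). Their adjusted p values were 0.0121 and 0.00202, and those of muc5.1, crb3b and fgfbp2b were 0.0254, 0.0014 and 0.0152. Without col9a2+ library 2 the log2 differences of lratb.2 and hpcal4 were 7.97 and 7.03, and PRKG2 and RASSF4 kept only 1 and 3 counts in col9a2+ libraries. PRKG2 differed by 7.10 without col9a2+ library 3 and RASSF4 by 6.98 without col9a2+ library 1. The differences of muc5.1 and fgfbp2b were -9.91 and -8.71 without col9a2+ library 1, and that of fgfbp2b was -9.12 without double-positive library 3. Those of MFAP4 and oclnb, -10.8 and -9.82, were -11.84 and -10.87 without double-positive library 2, and -10.06 and -9.1 without double-positive library 3.

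The count of 674 genes was 1024 with the replicate number as a block in all 9 libraries and 2228 in the 6 libraries of these populations, 1314 with the depth groups as a term, and 242, 270, 373 and 347 without col9a2+ library 1, 2 or 3 or double-positive library 2. Of 81 genes named by rule 33 kept their calls without each library in turn, and the fold of 33 moved by over 1.5 times without at least 1 library. Of those described here, the calls of RUNX2, enpp1, SLC20A1, snorc, krt18a.1, krt8, CYP26B1, ihhb, SPRY2, NOTCH1, mki67, MCM4, HOXA11, PRRX1 (ENSDARG00000033971), PRKG2, optc, RASSF4, mespbb, muc5.1, muc5.2 and fgfbp2b were lost without at least 1 library.

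The comparison of entpd5a+ with double-positive cells asks which genes separate cells with the entpd5a reporter alone from cells with both. In entpd5a+ cells 10 of 27 notochord genes fell, while 10 of 27 bone genes and 12 of 30 tendon, fibroblast and sclerotome markers rose. The SHH genes ENSDARG00000068567 and ENSDARG00000038867 fell by 3.98 ± 0.48 and 4.72 ± 0.56, 15.8-fold from 1294 ± 227 CPM and 26.3-fold from 606.5 ± 227.6 CPM (adjusted p = 0.00326 for each). The osteoblast factor runx2b rose by 3.69 ± 0.60 from 10.3 ± 6.27 CPM (adjusted p = 0.00795). The test called 1239 genes, 583 higher and 656 lower, with no overlap between libraries in any of them, against 26.1% of all genes tested.

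Of 27 notochord genes 10 fell and 1 rose, and 16 fell and 1 rose adjusted over the list alone. The keratin gene krt94 fell by 3.42 ± 0.50 (adjusted p = 0.00557, and -4.03 without entpd5a+ library 3), and krt18b rose by 2.71 ± 0.48 (adjusted p = 0.0114). Camera put the list lower (adjusted p = 2.55e-08), but not with an estimated correlation (adjusted p = 0.262). Of 27 bone genes 10 rose and none fell, and 22 rose adjusted over the list alone. The factor DLX3 rose by 2.87 ± 0.45, scpp1 by 3.22 ± 0.55 and COL5A1 by 3.36 ± 0.62 (adjusted p = 0.00731, 0.0103 and 0.0127). Camera put the bone list higher (adjusted p = 2.81e-12), but not with an estimated correlation (adjusted p = 0.243). Mineral and phosphate genes went in both directions, with 6 rises and 5 falls among 28. PHEX rose by 3.27 ± 0.60 and PHOSPHO1 by 3.30 ± 0.65, while mgp, a mineralization inhibitor, fell by 3.50 ± 0.61 and ANXA6 by 3.24 ± 0.46 (adjusted p = 0.0126, 0.0172, 0.011 and 0.00514).

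Of 30 tendon, fibroblast and sclerotome markers 12 rose and none fell, and 22 rose and 2 fell adjusted over the list alone. PDGFRA, a receptor of mesenchymal cells, rose by 3.65 ± 0.55, twist1b by 3.28 ± 0.54, and the 2 genes named PRRX1 (ENSDARG00000042027 and ENSDARG00000033971) by 3.38 ± 0.40 and 3.48 ± 0.48 (adjusted p = 0.00636, 0.00878, 0.00326 and 0.00473). Without double-positive library 1 PDGFRA and twist1b differed by 4.29 and 4.03. Camera put the list higher (adjusted p = 1.89e-10), but not with an estimated correlation (adjusted p = 0.323). Of 55 matrix remodelling genes 15 rose and 8 fell. COL6A2 rose by 3.83 ± 0.52 and MMP2 by 3.31 ± 0.47, while col4a6 fell by 3.00 ± 0.31 and col4a5 by 2.57 ± 0.30 (adjusted p = 0.0044, 0.00513, 0.00294 and 0.00326). Of 46 Hox genes 10 rose and 2 fell. HOXB13, HOXC13 and hoxa9b rose by 3.12 ± 0.45, 3.14 ± 0.55 and 2.25 ± 0.42, and HOXB5 fell by 2.30 ± 0.43 (adjusted p = 0.00541, 0.011, 0.0133 and 0.014). Cartilage genes were mixed, with 5 rises and 8 falls among 29, as snorc fell by 4.35 ± 0.53 and chad by 3.28 ± 0.44 while MATN4 rose by 3.40 ± 0.48 (adjusted p = 0.00326, 0.00404 and 0.00524, and 4.02 for MATN4 without double-positive library 3).

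In the BMP and TGF-beta list 11 of 53 rose and 9 fell. BMP5 rose by 4.49 ± 0.53, while TGFBR3 fell by 3.24 ± 0.37 and SOST, a BMP and Wnt antagonist, fell by 3.87 ± 0.67 from 190.6 ± 95.2 CPM (adjusted p = 0.00326, 0.00326 and 0.0108). In the Wnt list 7 of 48 rose and 6 fell, with LEF1 13.0-fold higher (adjusted p = 0.00326) and TCF7L2 9.25-fold lower (adjusted p = 0.00341), both transcription factors of the pathway. In the hedgehog list 4 of 20 rose and 3 fell, and the indian hedgehog genes went apart, ihhb down by 3.76 ± 0.48 and ihha up by 3.78 ± 0.64 (adjusted p = 0.00349 and 0.00963, and for ihha 3.00 without entpd5a+ library 2 and 4.37 without double-positive library 3). In the retinoic acid list 4 of 27 rose and 4 fell, including a fall of ALDH1A2 by 2.27 ± 0.33 (adjusted p = 0.00557) and a rise of RBP4 by 2.01 ± 0.37 (adjusted p = 0.0124). In the FGF list 5 of 31 rose and 1 fell, with fgfr4 up 7.80-fold (adjusted p = 0.0151, and a log2 difference of 2.31 without entpd5a+ library 2). No member of the Notch list passed edgeR's test, of 36 measured, while 13 had an unadjusted p under 0.05 and DESeq2 called 11. Of 56 genes of procollagen processing and secretion 3 rose and 1 fell, including a rise of the collagen chaperone gene SERPINH1 by 1.94 ± 0.31 (adjusted p = 0.00727).

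Among the largest rises CRHBP reached 20.9 ± 22.8 CPM, the proteoglycan gene ASPN 369.0 ± 326.3, the activin antagonist gene FST 41.4 ± 13.2, ABTB3 22.8 ± 8.45 and CYP26A1 69.7 ± 106.3 CPM (adjusted p = 0.014, 0.041, 0.0147, 0.0195 and 0.0419), and ANGPTL5 was 42.2-fold higher (adjusted p = 0.0228). Among the largest falls SLC29A1, a nucleoside transporter gene, was 29.7-fold lower, rxfp3 44.9-fold, birc5b 34.2-fold and CBLN4 32.7-fold (adjusted p = 0.00326, 0.014, 0.0239 and 0.0368). PRKG2 and optc fell by 6.41 ± 1.63 and 5.82 ± 1.16 (adjusted p = 0.0469 and 0.0175). Without entpd5a+ library 3 the log2 differences of PRKG2, CBLN4, CYP26A1, optc and rxfp3 were -9.40, -6.97, 1.97, -6.89 and -6.56, and without double-positive library 3 those of ANGPTL5 and ASPN were 7.41 and 9.13. Leaving out entpd5a+ library 1 took ANGPTL5, ASPN and birc5b to 4.70, 5.88 and -6.29, and birc5b and ABTB3 differed by -4.34 without double-positive library 2 and by 6.52 without double-positive library 1. CRHBP had 6 counts in double-positive library 2 and 0 in the other double-positive libraries, and its difference of 8.78 was 7.36 without entpd5a+ library 1 and 8.08 without double-positive library 3. Neither CYP26A1 nor PRKG2 passed with the depth groups as a term (adjusted p = 0.0837 and 0.0541).

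The count of 1239 genes was 525 without entpd5a+ library 2, 551 without double-positive library 2 and 455 in the 5 shallower libraries alone, again with 1 entpd5a+ library. Of 86 genes named by rule 58 kept their calls without each library in turn, and the fold of 25 moved by over 1.5 times without at least 1 library. Of those described here, the calls of PHOSPHO1, mgp, HOXB5, ASPN, FST, ANGPTL5, ABTB3, CYP26A1, birc5b, CBLN4, PRKG2 and optc were lost without at least 1 library.

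Comparing the double-positive population with both others asks whether it has genes of its own. It stood above both in 166 genes and below both in 128, and 13 genes stepped across the 3 populations, 11 rising towards entpd5a+ and 2 falling. Independent lists of these sizes would give 11 genes above both, 10.9 below both and 22 stepwise, 9.8 rising and 12.2 falling. The comparisons share the double-positive libraries, so the lists are not independent. In 20 simulations with no effect the mean and highest counts of all 3 patterns were 0. Those simulations called at most 1 gene in either comparison, so they cannot show what sharing gives beside real effects. The genes above both with the largest smaller difference were PRKG2, optc, the Wnt antagonist gene SFRP5, col8a1a and loxl5b. SFRP5 stood at 517 ± 200 CPM against 23.2 ± 20.7 in col9a2+ and 22.6 ± 9.85 in entpd5a+ cells, and its log2 difference from col9a2+ cells, 4.48, was 5.53 without col9a2+ library 2. Those below both were oclnb, crb3b, FST, ANGPTL5 and the cartilage gene ucmaa, which stood at 0.488 ± 0.428 CPM and was 57.8-fold lower than in col9a2+ and 22.7-fold lower than in entpd5a+ cells (adjusted p = 0.0283 and 0.0448). The log2 difference of ucmaa from col9a2+ cells was -6.68 without double-positive library 3 and -5.12 without col9a2+ library 1, and that between entpd5a+ and double-positive cells 5.33 without double-positive library 3 and 3.75 without entpd5a+ library 1. The stepwise genes were led by slc8a4b, mmp23bb, SOD3, PLTP and alpi.1. From col9a2+ over double-positive to entpd5a+ cells SOD3, an extracellular superoxide dismutase gene, stood at 3.45 ± 2.09, 18.7 ± 8.62 and 149.0 ± 38.6 CPM, and the metalloprotease gene mmp23bb at 416.5 ± 106.7, 45.9 ± 9.71 and 6.86 ± 5.38 CPM. The first step of SOD3 was 3.05 instead of 2.44 without col9a2+ library 1, and the last of mmp23bb -3.60 instead of -2.74 without entpd5a+ library 1. Of the genes named for these patterns, loxl5b, oclnb and crb3b kept both calls without each library in turn, and the others lost a call without at least 1 library. With the replicate block in the 6 col9a2+ and double-positive libraries alone, FST, ucmaa and slc8a4b did not pass between these populations (adjusted p = 0.0879, 0.0844 and 0.05). Between entpd5a+ and double-positive cells ucmaa did not pass with the replicate block in all 9 libraries or with the depth groups as a term (adjusted p = 0.0531 and 0.0509).

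For the 510 genes higher in entpd5a+ than in col9a2+ cells, double-positive cells were called different from entpd5a+ cells alone in 225, from col9a2+ cells alone in 75 and from neither in 184. They were called different from both in 11, between the ends, and stood outside the ends in 15. Of the 445 lower genes these counts were 233, 93, 102, 2 and 15. A missing call does not show equal levels, as 12% to 20% of 4-fold changes were recovered in the simulated data. These counts therefore do not give the number of genes at intermediate levels. With the replicate block the counts of genes above and below both were 263 and 199, and with the depth groups as a term they were 341 and 257. Without col9a2+ library 1, 2 or 3, double-positive library 2 or entpd5a+ library 2, the genes above both numbered 73, 82, 96, 62 and 65, and those below both 54, 60, 76, 55 and 55. Without double-positive library 3 the genes below both numbered 198. Stepwise genes numbered between 1 and 28 when single libraries were left out.

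**Figure D3:**
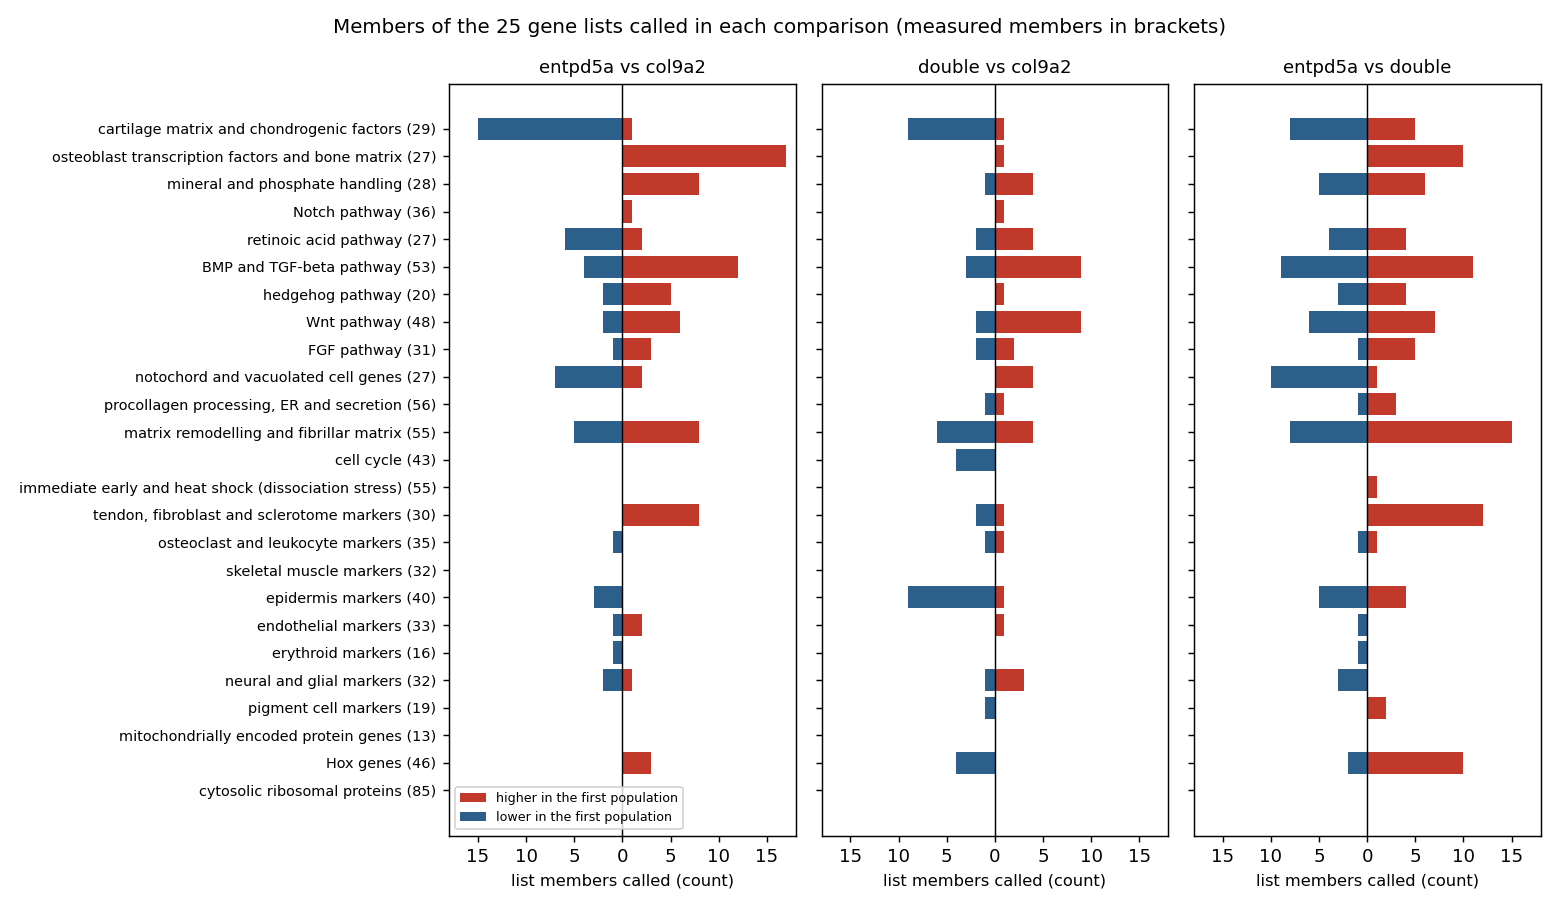
Number of members of each of the 25 gene lists called higher (red) or lower (blue) by edgeR in the population named before "vs" in each comparison, with measured members in brackets. Bone genes were called 17 times higher and never lower in entpd5a+ against col9a2+ cells, and cartilage genes 15 times lower and 1 time higher.

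The remaining lists cover other cell types and cell state. For entpd5a+ against col9a2+, double-positive against col9a2+ and entpd5a+ against double-positive cells in that order, the endothelial list had 2, 1 and 0 members higher and 1, 0 and 1 lower of 33. The osteoclast and leukocyte list had 0, 1 and 1 higher and 1, 1 and 1 lower of 35, the erythroid list 1, 0 and 1 lower of 16 (0 at an unadjusted p under 0.05 and 0 called by DESeq2 in the comparison with no edgeR call), the pigment cell list 0, 0 and 2 higher and 0, 1 and 0 lower of 19 (2 at an unadjusted p under 0.05 and 1 called by DESeq2 in the comparison with no edgeR call), and the neural and glial list 1, 3 and 0 higher and 2, 1 and 3 lower of 32. Besides the 9 falls and 1 rise in double-positive against col9a2+ cells, the epidermis list had 3 lower of 40 in entpd5a+ against col9a2+ cells, among them 2 genes named DSP, which encode a desmosome protein, and 4 higher and 5 lower in entpd5a+ against double-positive cells. The erythroid call was that of the membrane skeleton gene SPTB, which stood at 124.3 ± 66.2 CPM in col9a2+ and 147.8 ± 62.7 in double-positive cells. The endothelial rise in double-positive against col9a2+ cells was that of aplnrb, at 9.682, 0.5978 and 1.105 CPM in double-positive libraries 1, 2 and 3. Its log2 difference of 5.89 was 3.75 without library 1. It did not pass with the replicate block in all 9 libraries or with the depth groups as a term (edgeR adjusted p = 0.0641 and 0.0518). In the procollagen and secretion list P3H2 rose and CREB3L1 fell in double-positive against col9a2+ cells, by 2.86 ± 0.33 and 2.31 ± 0.33 (adjusted p = 0.00338 and 0.00698), and no gene passed edgeR's test in entpd5a+ against col9a2+ cells, where 8 had an unadjusted p under 0.05 and DESeq2 called 5. In the list of immediate early and heat shock genes HSPD1 alone passed, of 55, with a rise of 1.58 ± 0.40 in entpd5a+ against double-positive cells (adjusted p = 0.0457), a call lost without 8 of the 9 libraries in turn. In the other comparisons 9 and 3 of its genes had an unadjusted p under 0.05, and DESeq2 called 4 and 2. The cell cycle list had no edgeR call in entpd5a+ against col9a2+ and against double-positive cells, where 9 and 4 genes had an unadjusted p under 0.05 and DESeq2 called 3 and 2. The muscle list, of 32 genes, had no edgeR call in any comparison, with 0, 2 and 4 genes at an unadjusted p under 0.05 and 0, 1 and 3 called by DESeq2. For the 13 mitochondrially encoded and 85 ribosomal protein genes all of these counts were 0. Medians, means or camera directions differed in sign for the BMP and TGF-beta, retinoic acid, endothelial and erythroid lists in entpd5a+ against double-positive cells, for the Notch and mitochondrial lists in double-positive against col9a2+ cells, and for the erythroid and secretion lists in entpd5a+ against col9a2+ cells.

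With the preset correlation camera called further lists, whose p values are given in the order of the lists. In entpd5a+ against col9a2+ cells it put the mineral, Notch, BMP, Wnt, heat shock and tendon lists higher, with adjusted p = 4.74e-04, 8.29e-04, 3.30e-05, 3.86e-06, 0.00203 and 4.62e-07, but not with an estimated correlation (adjusted p = 0.202, 0.481, 0.481, 0.261, 0.738 and 0.481). In entpd5a+ against col9a2+ cells it put the notochord, cell cycle, epidermis and ribosomal lists lower, with adjusted p = 0.00185, 5.52e-05, 0.00187 and 4.74e-04, but not with an estimated correlation (adjusted p = 0.593, 0.329, 0.651 and 0.806). In double-positive against col9a2+ cells it put the BMP and notochord lists higher, with adjusted p = 1.96e-06 and 0.0062, but not with an estimated correlation (adjusted p = 0.461 and 0.593). In double-positive against col9a2+ cells it put the tendon, muscle and Hox lists lower, with adjusted p = 0.0266, 0.0494 and 0.003, but not with an estimated correlation (adjusted p = 0.7, 0.738 and 0.229). In entpd5a+ against double-positive cells it put the cartilage and ribosomal lists lower, with adjusted p = 0.0411 and 0.0021, but not with an estimated correlation (adjusted p = 0.593 and 0.826). In entpd5a+ against double-positive cells it put the Notch, Wnt, FGF, matrix remodelling, epidermis and Hox lists higher, with adjusted p = 0.00626, 0.0454, 0.00111, 0.00183, 0.0182 and 2.64e-04, but not with an estimated correlation (adjusted p = 0.593, 0.608, 0.261, 0.481, 0.7 and 0.201). With the depth groups as a term these calls were lost for the ribosomal list in entpd5a+ against col9a2+ cells (adjusted p = 0.132), the muscle list in double-positive against col9a2+ cells (adjusted p = 0.0721) and the cartilage, Wnt and ribosomal lists in entpd5a+ against double-positive cells (adjusted p = 0.103, 0.12 and 0.902).

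**Figure D4:**
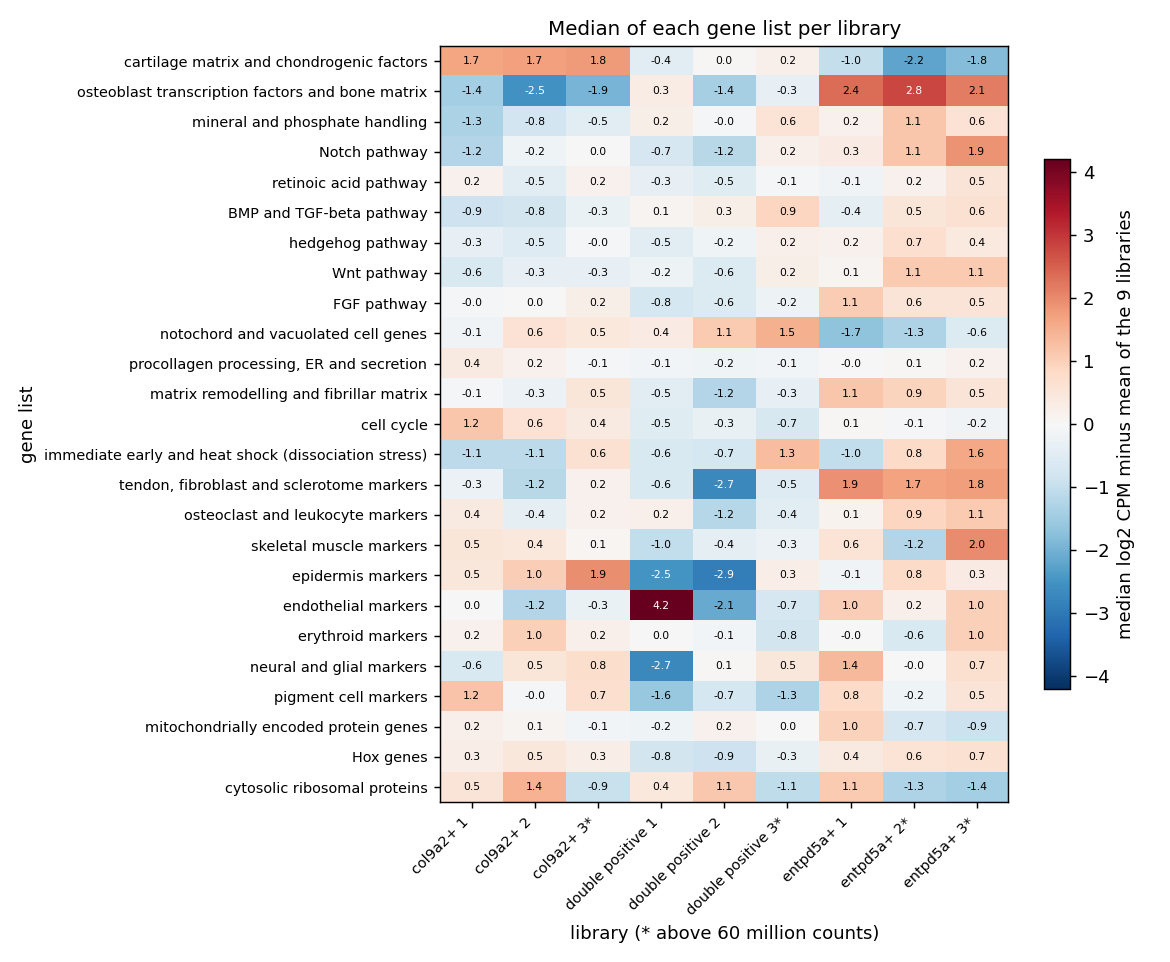
Median over each gene list of log2 CPM minus the gene's mean over the 9 libraries, by library, with an asterisk at the 4 deeper libraries. The heat shock and immediate early list is above 0 in those 4 libraries and below 0 in the 5 others, and the endothelial list stands at 4.17 in double-positive library 1.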

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

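The depth-group term, the 5 shallower libraries alone and the block in 6 libraries were chosen after seeing the data. None of the alternatives listed in the processing turned a called named gene to the opposite direction, and the axis position stayed within 1 SD, between 0.408 and 0.542 without single libraries. DESeq2 called 2159 genes for entpd5a+ against col9a2+, 2026 for double-positive against col9a2+, 2874 for entpd5a+ against double-positive and 3592 among the 3 populations, with 355 above both, 618 below both and 103 stepwise. It kept 951 of 955, 668 of 674 and 1235 of 1239 calls in the same direction. The replicate block gave 1024 genes for double-positive against col9a2+ (635 of the 674 kept), 263 above both, 199 below both and 37 stepwise, and in 6 libraries alone 2228 (623 kept). The depth-group term gave 1314, 341, 257 and 41. The 5 shallower libraries gave 202 genes for entpd5a+ against col9a2+ and 455 against double-positive, with 1 entpd5a+ library, which was assumed to vary like the other groups. A minimum fold of 1.5 left 632 genes for entpd5a+ against col9a2+, the 6 libraries alone gave 758 for entpd5a+ against double-positive, and a mean of at least 10 CPM gave 21 stepwise genes. Without single libraries the counts ranged from 353 to 994, 242 to 787 and 525 to 1064 in the pairwise comparisons in the order above, from 1084 to 1788 among the 3 populations, 62 to 156 above both, 54 to 198 below both and 1 to 28 stepwise. Of 34 list calls fry lost 18, the depth-group term 5 and the block 2. The cause of these shifts was not tested beyond the fewer samples or genes of some settings. In the simulated data, with a recovery of 12% to 20% at 4-fold, smaller changes were mostly not detected. The simulation changed 200 genes per comparison, fewer than the real comparisons called. All changed genes had a mean of at least 5 CPM. Recovery in the real data may therefore differ.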

Other observations

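All tests of explanations below, apart from the counts over other splits of the libraries, were chosen after the results were seen. The predictions for all of them, the splits included, were written after the results.

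Some abundant genes lay outside the rule for named genes and were chosen after their values were seen. The 2 genes named COL10A1, a collagen of hypertrophic cartilage and of fish bone, rose from col9a2+ to entpd5a+ cells. ENSDARG00000054753 stood at 1284 ± 992 CPM in col9a2+, 7151 ± 5070 in double-positive and 50300 ± 18320 in entpd5a+ cells (SD, n = 3 libraries; log2 difference of the ends 5.29, edgeR adjusted p = 0.00971). ENSDARG00000101535 stood at 598 ± 337, 2787 ± 2210 and 19450 ± 7170 CPM (5.02, edgeR adjusted p = 0.0103). The mineral-binding protein gene spp1 stood at 65.5 ± 48.7, 304.8 ± 241.3 and 2362 ± 616 CPM and rose by 5.17 (edgeR adjusted p = 0.0108). The osteoblast factor SP7 stood at 9.07 ± 9.34, 24.9 ± 16.7 and 199.4 ± 122.9 CPM and rose by 4.46 (edgeR adjusted p = 0.0223). The gene otos2 stood at 11050 ± 7633, 1188 ± 723 and 144.2 ± 229.0 CPM, and its difference of -6.26 did not pass (edgeR adjusted p = 0.0519).

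Heat shock and immediate early genes were higher in the 4 deeper libraries, which come from all 3 populations, with JUN between 4376 and 10500 CPM against 454.5 to 1698 CPM in the others. The list was higher in the deeper libraries by 1.73, 1.99 and 2.24 log2 in col9a2+, double-positive and entpd5a+ cells. The ribosomal protein list, which is not part of the pattern, differed by -1.93, -1.85 and -2.46. A handling or library batch across the populations, which the labels do not name, would also give this. The lower ribosomal share of these libraries had already been seen, so this is not an independent test. A difference between populations is argued against as the source of this pattern. The list was higher in the deeper libraries inside each population, and every deeper library stood above every shallower one, by at least 1.26 log2. Whether the populations also differ cannot be told. A share of 0.152 of the variance of the list median lay between them, which 147 of all 280 splits of the libraries reached. Because entpd5a+ has 2 deep libraries and the others 1, its comparisons carry part of the depth difference.

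In entpd5a+ against double-positive cells 10 of 27 bone genes rose, and 10 of 27 notochord genes fell and 1 rose by edgeR, with camera at adjusted p = 0.243 and 0.262 with an estimated correlation. The depth groups are argued against as the whole source, since 15 bone genes were higher and 14 notochord genes lower with a depth-group term. Cells from outside the notochord, such as osteoblasts on its surface, which a gate on entpd5a would not remove, may contribute, since 12 of 30 tendon, fibroblast and sclerotome genes were higher and 0 lower by edgeR. That evidence is limited, as 18 of the 30 genes reached 10 CPM in col9a2+ or double-positive cells and none is in the bone list. Sheath cells in a bone-forming state cannot be told apart from this, because the 10 notochord genes that fell are predicted by both.

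The double-positive cells stood above both other populations in 166 genes. A mixture of col9a2+ and entpd5a+ cells is argued against, since of genes chosen in 2 libraries per population 97.3% stood above both others in the 3 libraries left out, in CPM without scaling factors, where a mixture allows at most 50%. The lowest share was 93.8% over the 11 of 27 ways to leave libraries out that chose at least 20 genes, and without double-positive library 2 or entpd5a+ library 2 none was chosen. RNA of another cell type in double-positive library 1, which held endothelial transcripts, is argued against, since 111 genes kept both calls without it. Other cell types in all double-positive libraries stay open, as 4 members of 7 marker lists (mbpb, pkp1a, rtn1b and WAS) were among the genes against 1.8 expected of 206. A state of the double-positive sheath cells themselves was not tested.

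Over the 3 populations 60 of 280 possible splits of the 9 libraries into groups of 3 were drawn, and 1 of them, the real one, gave as many as 1792 genes. The highest of the others drawn gave 249, which argues against a random grouping as the source of that count (share 0.0167). It is not excluded, as the remaining splits were not examined. The splits also treat the libraries as exchangeable despite the depth groups. Each pairwise comparison has 10 splits, too few for a share under 0.05. The real splits gave 955, 674 and 1239 genes and the highest others 0 in each.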
